A study of Homo sapiens with 6 samples.

How the data were processed

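ERα-bound regions were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in MDA-MB-453 cells, an established human breast cancer line that expresses the androgen receptor and makes no functional ERα of its own. Per the labels' protocols, the cells carried a doxycycline-inducible wild-type, Y537S or K303R ERα. They were plated in medium with 10% fetal bovine serum, grown for 2 days, and then grown for 2 days with 2 µg/mL doxycycline, without or with 1 nM estradiol (E2). The labels do not say that the serum was stripped of hormones. Chromatin from 2 plates was precipitated with the anti-ERα antibody D8H8, libraries were made from 2 ng of DNA, and paired reads of 75 bp were sequenced. Each of the 6 combinations of receptor and treatment has 1 library, taken from the sample titles, so there are no replicates.

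The submitters' processing notes name Bowtie2, SAMtools, Picard, bedtools and MACS2 and the genome build hg38, with no versions or roles. The control library, the peak threshold and the read filters are not given in the sources used here. Each library has its own list of peaks. For each peak the authors' list gives its position, its summit, a fold enrichment (a ratio to the local background), a −log10 p-value, a −log10 q-value and a score. The deposited score is 10 times the −log10 q-value, rounded down, in over 99% of entries, and was not used. The fold and the p-value are the authors' own values for each peak. They were used to rank and filter regions within a list, and to recover counts as described below. Total read counts per library are not given in the lists, so sequencing depth is not known directly.

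Peak names carry a date-like tag that the wild-type and K303R lists share and that differs in the Y537S lists. A processing batch may therefore coincide with the Y537S line, and no comparison of Y537S with wild type can be made within a tag. The comparisons of E2 with no E2 each lie within 1 tag, as do those of K303R with wild type.

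Regions on chromosomes 1 to 22 and X were analysed. No 2 entries of a list shared coordinates. The tests were fixed before the data were examined. They were the number of regions per library, the overlap of each pair of lists, the strong regions of one list that overlap no region of another, the presence of mutant regions in the wild-type E2 list, the location of summits, the number of listed genes near strong regions, and the regions at ESR1 and at vector promoter genes. A strong region is 1 of the 10000 regions with the highest −log10 p in its library. An overlap is at least 1 bp. Pairs of lists were compared by the Jaccard index, the shared bases over the covered bases. An exact permutation test set the 3 same-receptor pairs against the 15 ways to match 6 libraries into pairs. Changes with E2 were tested over the 3 lines with an exact 2-sided sign-flip test, whose smallest p is 0.25.

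No genome sequence was used here, and the gene table (GRCh38.p14) gives gene spans without strand or exons. Several parts of the fixed plan were changed for that reason. The 15 motifs chosen in advance were not searched. A summit was placed within 1 kb of either end of a protein-coding or lncRNA gene instead of a transcription start site. A gene was called near a strong region when a summit lay in its span or within 25 kb of it, instead of within 25 kb of its 5′ end. ESR1 was examined over its whole span. Exon, intron and UTR positions were not analysed here.

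The 10 gene lists, with 240 genes, were fixed before the data were examined. All 240 genes were matched, 1 of them through an older symbol, and no gene is in 2 lists. The number of list genes near a strong region was set against 10000 random lists of protein-coding genes matched on local gene density and gene length. The percentile describes these libraries and is not a test between them.

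A further analysis was chosen after seeing the data. The fold and the −log10 p of a peak are both set by the number of fragments at its summit and by the local background. For a Poisson p-value and a pseudocount of 1 in the fold, solving the 2 equations gave a whole number of fragments. The deposited p was matched to within 0.01% for 99.9% to 100.0% of regions in each library. On simulated peaks the number was recovered in all cases. Summit fragments were compared between libraries at merged regions with a mean of at least 50 fragments over the 6 libraries, found in all 6 lists (33626 regions, called well covered here). Ratios were centred on the median of each library over these regions. A region was counted as higher or lower when its ratio passed 1.5-fold and its exact 99.9% counting interval excluded 1. Such a call compares 2 libraries, not 2 conditions, and has no replicate check. Intervals cover counting error only. In simulated libraries with changed regions, calls for E2 in wild type recovered 85.0% of 2-fold and 100% of 3-fold changes, those for E2 in Y537S 84.0% and 100%, and those for E2 in K303R 73.0% and 100%. Counting noise was simulated in 100 draws that split each region's total with no change. Each library's value at a merged region is that of its own highest summit there, so 2 libraries may be counted at different positions. The draws and the intervals leave this out.

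The summit fragments have limits. The highest count in a library was 0.950 to 0.989 of 2 times the narrowest region's width, which was never exceeded. That is the pattern of a limit on distinct fragments per position, so ratios at the strongest regions are compressed. The recovered local background also followed the library's own signal (r of 0.65 to 0.89 between the ratios of both), so the fold was not compared between libraries.

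Genes were named by the rule fixed in advance. It takes up to 20 estrogen receptor targets near a strong region by the highest −log10 p, the 3 highest genes of each other list, up to 10 strong regions per comparison absent from the other list, the 5 highest regions per library, and ESR1, PGK1 and EEF1A1. Some genes that the rule picks are left out of the text. Regions named for a ratio of summit fragments were chosen after their values were seen. They come from the 12 per direction with the greatest smaller one of their 2 ratios. Their names are those of the nearest protein-coding gene. Alternatives changed the threshold, the number of strong regions, the ranking, the overlap, the windows, the scaling and the minimum count. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.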

Results

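Binding of ERα was measured in MDA-MB-453 cells that expressed wild-type ERα, Y537S or K303R under doxycycline. Y537S is a substitution in the ligand-binding domain that makes the receptor active without hormone, and K303R lies in the hinge region. The 6 libraries combine the 3 receptors with growth without or with 1 nM E2, with 1 library per group. The comparisons ask which regions each receptor bound without hormone, what E2 added, and how the mutants differed from wild type. Without replicates no difference below has a replicate check, and printed intervals are 95% intervals that cover counting error only.

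All 6 libraries held a large set of bound regions. The wild-type list had 125850 regions without E2 and 121718 with E2, the Y537S lists had 117193 and 112464, and the K303R lists had 106186 and 107137. The regions covered 48.0 to 57.1 Mb, with a median width of 401 to 419 bp. With E2 the number fell by 4132 in wild type, fell by 4729 in Y537S, and rose by 951 in K303R (exact sign-flip p = 0.5, smallest possible 0.25). After merging, 67735 of 175206 regions (38.7%) were in all 6 lists and 38003 (21.7%) in 1 list only. The median highest summit held 72 fragments for the former and 11 for the latter.

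Lists of the same receptor resembled each other more than other pairs did. The Jaccard index was 0.650 for the wild-type pair, 0.678 for the Y537S pair and 0.619 for the K303R pair, with a mean of 0.649 against 0.577 for the other pairs. Of 15 ways to match the libraries into pairs, only the matching by receptor reached that mean (exact permutation p = 0.0667, the smallest possible). For libraries of the same treatment the mean was 0.579, and 7 of 10 splits gave as high a value (exact permutation p = 0.7). The split by treatment holds no same-receptor pair, while most of the other splits do. This p therefore follows from the likeness of same-receptor lists and cannot tell whether lists of the same treatment were alike.

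Known estrogen receptor targets were bound in all libraries, including those without E2. Of 45 listed targets, 33 lay within 25 kb of a strong region in wild type without E2 and 37 with E2. The counts were 34 and 32 in Y537S and 34 and 37 in K303R, while random lists had a median of 13 or 14. The count was above that of the 10000 random lists in each library (percentile 100). In all, 40 targets were near a strong region in at least 1 library and 28 in all 6. CXCL12, EGR3, OLFM1, RBBP8 and UGCG were near none.

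The strongest target regions changed little with E2. GREB1, an early estrogen-response gene, had 307 summit fragments in wild type without E2 and 289 with E2 (ratio 0.923, interval 0.783 to 1.09) at chromosome 2, 11498327 to 11499045, inside the gene span. At the progesterone receptor gene PGR (chromosome 11, 101033887 to 101034632, inside the span) the counts were 327 and 331 (0.992, 0.849 to 1.16). The strongest region within 25 kb of TFF1, which encodes a secreted trefoil peptide, lay in the neighbouring gene TMPRSS3 (chromosome 21, 42376200 to 42376784), with 238 and 232 fragments (0.956, 0.794 to 1.15). XBP1, a transcription factor of the unfolded protein response, had 348 and 340 fragments at a region 13425 bp outside its span (chromosome 22, 28813569 to 28814418; 0.958, 0.822 to 1.12). The chaperone gene FKBP4, the transporter genes SLC22A5, ABCA3 and SLC7A5, and SIAH2, NHERF1, PDZK1, TPD52L1, FHL2, CCN5, RARA, IGFBP4, CTSD, ELOVL2, MYB and RET were also near a strong region in all 6 libraries. Their wild-type E2 ratios ranged from 0.886 at RET to 1.13 at IGFBP4.

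Other gene lists were closer to random lists. Luminal epithelial genes near a strong region numbered 9 to 14 of 24 per library (percentiles 83.0 to 99.9), with the highest −log10 p at GRHL2, ELF3 and RAB25. Androgen receptor and apocrine genes numbered 10 to 15 of 30 (percentiles 53.6 to 97.8), with high −log10 p at PMEPA1 and NDRG1. Receptor tyrosine kinase and PI3K genes numbered 9 to 11 of 17 (88.8 to 98.3), led by ERBB2, AKT1 and WNT7B. Basal and mesenchymal genes numbered 6 to 9 of 20 (50.9 to 92.5), led by TP63, COL1A1 and SNAI1. Cell cycle genes numbered 4 or 5 of 22 (13.4 to 31.3), led by MCM5, CDC6 and RRM2, and the CDC6 region lies in its neighbour RARA. Housekeeping genes numbered 6 to 8 of 22 (57.9 to 84.7), with high −log10 p at YWHAZ and HSP90AB1. Of the lists for other cell types, hepatocyte genes numbered 9 to 11 of 20 (97.3 to 99.6), led by SERPINA1, F2 and FGA. Neuronal genes numbered 6 or 7 of 20 (33.1 to 52.0), led by CAMK2A, GRIN1 and NEUROD2, and immune genes 6 to 8 of 20 (54.8 to 87.6), led by LCP1, NKG7 and ITGAM. With the strongest 5000 regions the luminal percentiles ran from 28.1 to 92.5, and the hepatocyte ones from 99.4 to 99.9. With a window of 100 kb the hepatocyte percentiles ran from 63.3 to 88.7.

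The 5 strongest regions of each library recurred between libraries. A region 81143 bp from RGS9 on chromosome 17 was among the 5 in 3 libraries, and regions inside MECOM and near AXIN2 and RD3 each in 3 or more. In wild type with E2, 2 of the 5 lay near the cyclin gene CCND1 on chromosome 11, at 86030 bp (69554815 to 69555439) and 64884 bp (69575859 to 69576625) from its span. The former region was also among the 5 in K303R with E2.

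No strong region with E2 was wholly absent from the same receptor's list without E2. Of the 10000 strongest regions with E2, 0 were absent from the list without E2 in wild type, in Y537S and in K303R, and the same held in the other direction (0%, upper bound of the Wilson interval 0.0384%). The weakest strong region had a −log10 p of 83.7 to 129 per library, while the lists reach down to 5 or 6 summit fragments. Only a very large fall could make a strong region absent, so these 0 counts say little about smaller changes with E2. Regions ranked by fold gave 2 in K303R with E2. Among the strongest 50000, a number chosen after seeing the data, 69 wild-type E2 regions were absent without E2 and 56 the other way. The counts were 26 and 24 in Y537S and 617 and 312 in K303R.

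Summit fragments showed regions, weak without E2, that were higher with E2 in wild type and in K303R but not in Y537S. At a region inside NOL12 (chromosome 22, 37688513 to 37689311), wild type had 10 fragments without and 60 with E2 (5.88-fold, 2.99 to 12.9). K303R had 21 and 91 (3.51-fold, 2.17 to 5.95), and Y537S had 178 and 176 (0.874, 0.706 to 1.08). MAPKAPK3, a kinase of the stress-activated p38 pathway, had 14 and 62 fragments in wild type (4.34-fold, 2.40 to 8.40) and 16 and 65 in K303R (3.30-fold, 1.88 to 6.10). In Y537S it had 99 and 119 (1.06, 0.807 to 1.40; chromosome 3, 50647558 to 50648257). A region in DUOX2, a hydrogen peroxide-producing oxidase, had 29 and 80 fragments in wild type, 26 and 84 in K303R, and 81 and 88 in Y537S (chromosome 15, 45101937 to 45102365). RIBC2, the calcium pump gene ATP2B2, the chloride channel gene ANO1 and CLIP2 held regions of the same kind, as did LHPP, whose ratio in Y537S was 1.49 (1.11 to 2.00), under the 1.5-fold needed for a call. Fewer regions were lower with E2 in both. They included regions in FRMD6 (0.481 in wild type, 0.406 in K303R) and in the amino acid transporter gene SLC38A4 (0.519 and 0.481), and one 543141 bp from TBX3 (0.495 and 0.533).

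**Figure D1:**
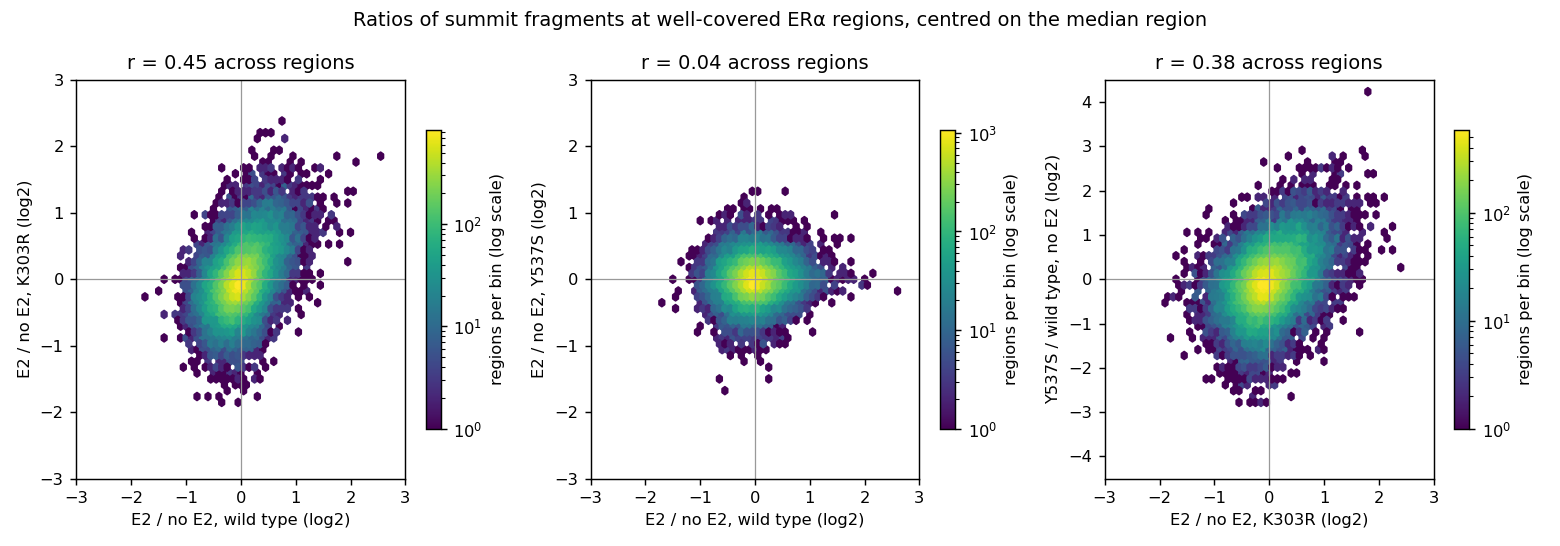
Each panel bins the 33626 well-covered regions by 2 log2 ratios of summit fragments, centred on the median region. The E2 ratios of wild type and K303R rose together (r = 0.45), those of wild type and Y537S hardly did (r = 0.04), and the K303R E2 ratio rose with the ratio of Y537S to wild type without E2 (r = 0.38).

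Of 33626 well-covered regions, 520 were higher and 230 lower with E2 in wild type, where counting noise gave means of 10.5 and 9.46. In K303R 691 were higher and 354 lower (noise 11.03 and 11.66), and in Y537S 29 and 28 (noise 10.0 and 10.4). The spread of the E2 log2 ratios was 1.51 times that of counting noise in wild type, 1.62 times in K303R and 1.09 times in Y537S. The sets of wild type and K303R shared 125 higher regions, where independent lists would share 10.7, and 14 lower regions (2.42 for independent lists), and no region went opposite ways (5.47 and 4.73). Scaled by the lowest local background they shared 601 higher and 0 lower regions. Across regions, which are not independent replicates, Pearson's r of the E2 ratios was 0.45 between wild type and K303R (jackknife error over chromosomes 0.0131). It was 0.04 between wild type and Y537S (0.00636) and 0.07 between K303R and Y537S (0.00673). No library is shared in these pairs, but wild type and K303R share a peak-name tag, and both pairs with Y537S cross it. Receptor and tag therefore cannot be told apart in this difference between the pairs. Ratios are relative to the median region. Scaled by the lowest local background instead, the median log2 E2 ratio was 0.09 in wild type, −0.01 in Y537S and 0.36 in K303R, and the higher and lower regions numbered 904 and 79, 29 and 29, and 4698 and 13.

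Well-covered regions that E2 raised in K303R were mostly higher in Y537S than in wild type without E2. The 691 regions were picked by the K303R libraries, but among the well-covered ones, whose minimum mean includes the Y537S libraries. Over them the median ratio of Y537S to wild type without E2 was 1.54, and 81.2% lay over 1. Over all well-covered regions these values were 0.960 and 44.8%. With E2 the median ratio at the 691 regions was 1.11. At the 354 regions that were lower with E2 in K303R, the median ratio without E2 was 0.752. The higher sets shared 275 regions (55.6 for independent lists), the lower sets 96 (32.4), and r across regions was 0.38 (error 0.00870). A region with few K303R fragments without E2 (mean 43.8 over the 691) passes the minimum more easily where Y537S is high. How far this adds to these values was not tested. The ratio of Y537S to wild type also crosses the peak-name tag.

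Some regions that the mutants added to the wild-type list without E2 were in the wild-type E2 list. Of 21398 Y537S regions absent from the wild-type list without E2, 32.2% (31.5 to 32.8) were in the wild-type E2 list. For 16124 K303R regions the share was 26.4% (25.8 to 27.1). Neither share was set against a chance value. The wild-type lists differed both ways, with 85.4% of E2 regions overlapping the list without E2 and 82.2% the other way. The 17769 wild-type E2 regions absent without E2 were examined in the mutants. Of these, 38.8% were in the Y537S list and 24.3% in the K303R list without E2. They were weak, with a median −log10 p of 8.39 against 25.9 for the others.

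Y537S differed from wild type at many regions, with or without E2. A region in PLXNB2, a plexin receptor gene, had 24 fragments in wild type and 146 in Y537S without E2 (6.14-fold, 3.97 to 9.90). With E2 it had 26 and 173 (6.06-fold, 4.00 to 9.54; chromosome 22, 50281604 to 50282328). TBC1D9 (7.65-fold without and 4.41-fold with E2), the transcription factor gene BCL11B (4.47 and 4.84), ZNF385D (4.59 and 5.79) and DNAH17 (3.86 and 3.66) held other higher regions. Lower regions included one 1363 bp from PIP, a secreted marker of apocrine cells, with 74 fragments in wild type and 17 in Y537S without E2 (0.232, 0.128 to 0.397). With E2 it had 65 and 12 (0.168, 0.0827 to 0.314; chromosome 7, 143130481 to 143130947). THSD4 (0.236 and 0.242), RNLS (0.234 and 0.242), HTT (0.148 and 0.212) and OSBPL9 (0.207 and 0.206) also had lower regions, as did the phosphatase gene PTPRK (0.226 and 0.161) on chromosome 6.

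In both treatments 1124 regions were higher and 1609 lower in Y537S than in wild type, where independent lists would share 164 and 264. The ratios without and with E2, which share no library, had r = 0.75 across regions, and 1 region went opposite ways. Scaled by the lowest local background the numbers were 2673 and 640, and centred within 5 Mb windows 1136 and 1041. The direction of the split thus depends on the scaling and on regional trends. Both ratios compare the same pair of cell lines, so their agreement shows a line difference that held in both treatments, not a replicated receptor effect. Because the Y537S lists also carry a different tag from the wild-type lists, receptor, cell line and processing batch cannot be told apart here. By list membership 1 strong Y537S region without E2 was absent from wild type, at chromosome 5, 29949270 to 29949741, and there were 0 with E2 and 0 wild-type regions absent from Y537S in either treatment. Ranked by fold, 13 and 6 Y537S regions were absent from wild type, without and with E2, and 5 and 4 wild-type regions from Y537S.

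At estrogen receptor targets Y537S was low relative to its own median region. The median log2 ratio over 202 target regions was −0.18 without and −0.18 with E2, at percentiles 0.03 and 0.01 of matched random lists. Of the 202, 11 were called higher and 27 lower without E2, and 9 and 25 with E2, where 8.05% of all well-covered regions were called higher and 9.14% lower without E2. Scaled by background, the medians were 0.10 and 0.00, so the direction is relative to the median region. PGR had 168 fragments in Y537S against 327 in wild type without E2 (0.519, 0.428 to 0.627), TFF1 had 147 against 238 (0.624, 0.504 to 0.770), and GREB1 had 231 against 307 (0.760, 0.638 to 0.904). Within 5 Mb windows the target medians were −0.07 and −0.08. Low medians were not confined to this list. Those of housekeeping genes with E2 (−0.22, percentile 2.41), hepatocyte genes without E2 (−0.20, 2.61) and cell cycle genes with E2 (−0.20, 4.07) were as low.

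Chromosome 6 was low in Y537S over its whole length. Its median log2 ratio to wild type over 1643 regions was −0.40 without and −0.39 with E2, and without E2 its 20 Mb windows lay between −0.44 and −0.34. The median was −0.29 and −0.30 on the X chromosome, where windows without E2 ran from −0.60 to −0.07, −0.21 and −0.22 on chromosome 15, and 0.21 and 0.27 on chromosome 19. TPD52L1, ELOVL2, MYB and PTPRK lie on chromosome 6. K303R stood highest on chromosome 19, at 0.43 and 0.40. Chromosomes 8 (0.22 and 0.18) and 16 (0.19 and 0.20) were also high in K303R. Its lowest medians were on chromosomes 4 (−0.14 and −0.15) and 15 (−0.13 and −0.16). The cause of these K303R differences between chromosomes was not tested.

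**Figure D2:**
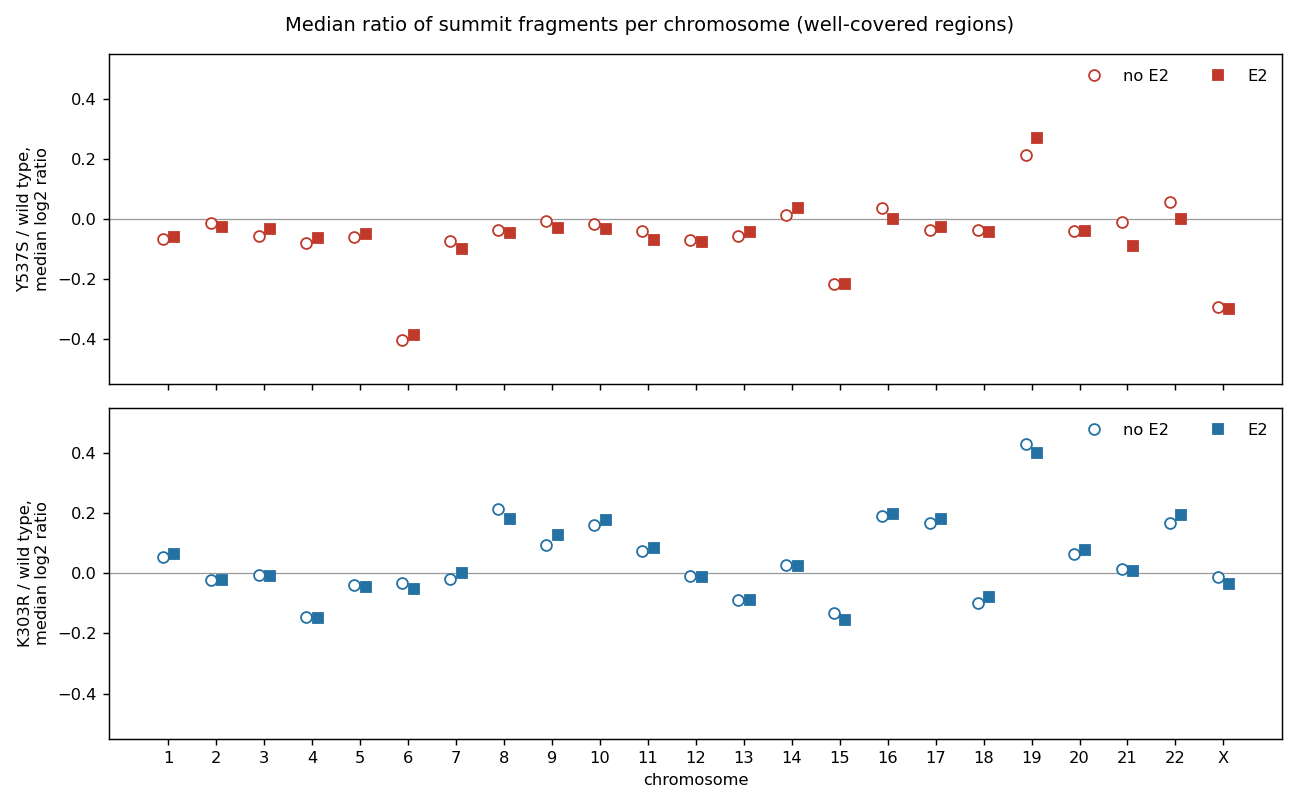
For each chromosome the points show the median log2 ratio of summit fragments to wild type, for Y537S (top) and K303R (bottom), without E2 (open circles) and with E2 (filled squares). Chromosome 6 lay at −0.40 and −0.39 in Y537S, and chromosome 19 at 0.43 and 0.40 in K303R.

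K303R also differed from wild type at many regions. Higher were a region 2068 bp from SLC45A3, an androgen-regulated transporter gene (4.84-fold, 3.20 to 7.52, without E2; 4.69-fold, 2.92 to 7.85, with E2; chromosome 1, 205655492 to 205656074), and one in GOT1, which encodes a cytosolic aspartate aminotransferase (4.31 and 3.69). NDUFAF6, a complex I assembly gene on chromosome 8, was also higher (3.26 and 3.17), while Y537S was lower than wild type there (0.324 and 0.310). At OLFML2B and SLC19A1, which held other higher regions of K303R, Y537S was above wild type too (3.80 and 3.22, and 3.37 and 2.34). Lower regions lay in KALRN, with 90 fragments in wild type and 8 in K303R without E2 (0.122, 0.0510 to 0.2504; chromosome 3, 124357581 to 124358259), and 86 and 14 with E2 (0.184, 0.0968 to 0.327). CADPS (0.194 and 0.189), MAP2K5 (0.196 and 0.191), the cadherin gene PCDH15 (0.191 and 0.202) and HS3ST2 (0.213 and 0.192) had others.

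In both treatments 869 regions were higher and 1191 lower in K303R than in wild type (117 and 155 for independent lists), with none in opposite directions and r = 0.75. Here too both ratios compare the same pair of cell lines, so receptor and cell line cannot be told apart. Scaled by the lowest local background, 155 were higher and 3026 lower. One strong wild-type region without E2 was absent from the K303R list, at chromosome 16, 60044401 to 60045069, and 42 were when ranked by fold. Estrogen receptor targets had median log2 ratios of 0.19 and 0.20, close to random lists (percentiles 55.7 and 56.6). For luminal genes the median was 0.34 without E2 (percentile 98.4) and 0.19 with E2 (58.4), and within 5 Mb windows 0.14 and 0.02. The other 8 lists lay between percentiles 15.9 (cell cycle) and 95.7 (receptor tyrosine kinase and PI3K) without E2, inside the range of 95% of random lists. Scaled by background the target medians were −0.24 and 0.06, and the luminal ones −0.10 and 0.06.

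Summits lay near gene ends in a minority of regions. Within 1 kb of either end of a gene were 11.7% of wild-type regions without and 11.3% with E2, 12.4% and 12.3% for Y537S, and 13.4% and 12.4% for K303R. The share was lower with E2 in 3 of 3 lines (exact sign-flip p = 0.25, the smallest possible). Inside gene spans lay 62.3% to 63.8%. Regions that were lower than wild type in both treatments were poor in gene ends, at 5.78% (4.74 to 7.03) for Y537S and 3.19% (2.33 to 4.35) for K303R. Higher regions held 16.3% (14.2 to 18.6) and 14.3% (12.1 to 16.8), against 10.6% of all well-covered regions. Both mutants were compared with the same wild-type libraries, so their shares are not independent observations.

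The ESR1 gene had about as many regions for its length as the genome. Over its span on chromosome 6, 151656672 to 152129619, there were 16 to 22 regions per library, or 3.37 to 4.63 per 100 kb, against 3.51 to 4.16 per 100 kb over the genome (4.63 against 4.02 in wild type with E2). Exons were not analysed here, so signal from the construct itself was not tested. In K303R 1 of them was a strong region in each treatment, at 151658016 to 151658647 without E2. The strongest one in wild type without E2 lay at 151658041 to 151658887. Its −log10 p of 86.3 was above the 83.7 of the weakest strong region in K303R without E2, but under the 115 of that in wild type. The label of a strong region thus depends here on the library's own ranking. With E2 the highest wild-type value was 92.6, also under the K303R bound of 105. PGK1 and EEF1A1, whose promoters are used in expression vectors, had 0 to 2 regions each within 1 kb of their spans, none of them strong, with at most 15 summit fragments (EEF1A1 in wild type without E2).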

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

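The items in this part were chosen by rules fixed in advance, and the opposite directions in it were not tested, since each group has 1 library. The number of regions changed with E2 in opposite directions between lines: −4132 in wild type, −4729 in Y537S and 951 in K303R. Estrogen receptor targets near a strong region changed by 4 in wild type, −2 in Y537S and 3 in K303R. TFF3 was among them with E2 in wild type and K303R and not without E2. The share of summits inside a gene span changed by −0.0157 percentage points in wild type, 0.2505 in Y537S and 0.179 in K303R.

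Sequences outside chromosomes 1 to 22 and X, which no comparison uses, held 19 regions in wild type without E2 and 22 with E2. There were 19 and 18 in Y537S, and 27 and 22 in K303R.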

How the results depend on the processing

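Alternatives named here as added, and all settings of the summit fragments, were chosen after seeing the data. The others were planned, and the planned motif alternatives (a window of 50 bp, all regions, no mismatch, flanks at 5 kb) were not run because no genome sequence was used. Of 134 planned values 94 stayed within their limit and 40 moved, and of 104 added ones 46 and 58. These are counts, shares and correlations, which can hardly change sign, but some splits into higher and lower turned. That of Y537S against wild type did under background scaling and under centring within 5 Mb windows, and the near-even E2 split of Y537S did in the correction for the limit and at 100 fragments. No paired analysis was possible because each group has 1 library, other than pairing the treatments over the 3 receptor lines, which was done only for the values with a sign-flip test. Unless said otherwise the cause was not tested. Same-receptor pairs kept the highest mean Jaccard index in all 3 planned settings (0.658 to 0.790).

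A −log10 q of at least 10 left 77335 regions in Y537S and 65469 in K303R without E2, by construction. Of strong regions absent from the other list, the strongest 20000 gave 4 of Y537S and 0 of K303R without E2, 1 of Y537S with E2, and, of wild type, 1 and 3 absent from Y537S and 12 and 13 absent from K303R, without and with E2. The strongest 5000 gave 0 of wild type absent from K303R without E2. Ranking by fold gave 13 and 6 of Y537S, 2 of K303R with E2 against wild type, 2 of K303R with E2 against no E2, and, of wild type, 5 and 4 absent from Y537S and 42 and 29 absent from K303R. An other list as short as the shortest gave 2 of Y537S without E2. Among the strongest 50000 (added) the E2 counts were 69 and 56 in wild type, 26 and 24 in Y537S, and 617 and 312 in K303R. Against wild type they were 742 and 419 of Y537S and 491 and 480 of K303R, and, of wild type, 675 and 533 absent from Y537S and 1523 and 1278 absent from K303R.

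Mutant regions found in the wild-type E2 list made up 36.6% (Y537S) and 30.9% (K303R) at a −log10 q of at least 5, and 23.3% for K303R with lists of equal length. Within 3 kb of a gene end, wider by construction, lay 21.005% and 20.8% of wild-type summits, 22.2% and 22.3% of Y537S and 23.2% and 22.6% of K303R. Of the strongest 10000, 8.88% and 8.90%, 9.98% and 10.1%, and 10.6% and 10.4% lay within 1 kb, and 64.5% and 64.6%, 66.2% and 66.0%, and 65.9% and 66.3% inside a gene span. With the strongest 5000, 21 estrogen receptor targets were near one in Y537S with E2.

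For summit fragments, scaling by the lowest local background gave 904 higher and 79 lower with E2 in wild type, 4698 and 13 in K303R, and 601 and 0 in both. In both treatments it gave 2673 and 640 for Y537S against wild type and 155 and 3026 for K303R. Correction for the limit on distinct fragments, which widens all ratios, gave 1028 and 593 with E2 in wild type, 122 and 136 in Y537S, 1299 and 731 in K303R, and 310 and 72 in both wild type and K303R. It gave 1909 and 2666 for Y537S against wild type and 1538 and 1764 for K303R. A mean of at least 100 fragments, which leaves 15599 regions, gave 155 and 56 in wild type, 2 and 6 in Y537S, 233 and 90 in K303R, 50 and 7 in both, 426 and 515 for Y537S against wild type and 272 and 489 for K303R. Centring within 5 Mb windows gave 1136 higher and 1041 lower for Y537S against wild type. It gave r of 0.420 (wild-type and K303R E2 ratios), 0.0281 (wild type and Y537S), 0.0458 (K303R and Y537S), 0.354 (K303R E2 with Y537S to wild type), 0.726 (Y537S to wild type in both treatments) and 0.703 (K303R). With at least 100 fragments the values were 0.483, 0.347, 0.771 and 0.771 for the first, the fourth, Y537S and K303R. Signed list medians did turn under background scaling, from −0.18 to 0.10 for estrogen receptor targets in Y537S against wild type without E2, from 0.19 to −0.24 for those in K303R, and from −0.18 to 0.22 for the luminal E2 ratio in K303R. Depth limits the weak regions most, since 10 fragments allow only wide intervals.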

Other observations

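Of the tests in this part, those on regional trends and on GC-rich DNA, and the values per gene list, were chosen only after the result was seen.

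With E2, luminal epithelial genes stood low in K303R. Over 72 regions near these genes, which include GRHL2, ELF3 and RAB25, the median log2 E2 ratio was −0.18 in K303R (percentile 0.07 of matched random lists), −0.09 in wild type (3.02) and −0.04 in Y537S (11.8). Receptor tyrosine kinase and PI3K genes, among them ERBB2, had −0.15 in K303R (percentile 0.41) and −0.03 in wild type (25.7), although 3 of their 60 regions were called higher and 0 lower with E2 in K303R. In K303R the other 8 lists lay between percentiles 11.2 and 92.6, with estrogen receptor targets at −0.04 (24.6). Within 5 Mb windows the luminal median in K303R was −0.07, and that of receptor tyrosine kinase and PI3K genes −0.16. Relative to background all of these K303R medians lie higher by one shift, and the luminal one is then 0.22.

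Of the regions named for low Y537S ratios, chosen after their values were seen, some lay close together. Near the cystatin genes CST9 and CST5 and near GGTLC1 on chromosome 20, 3 regions between 23595849 and 23970140 had ratios to wild type of 0.244, 0.189 and 0.186 without E2. Clustering of low regions was not tested.

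The E2 ratios of wild type and K303R went together in part, with r = 0.45 across regions and 125 shared among 520 and 691 higher regions. A regional trend along chromosomes is argued against as the whole of it, since r was 0.420 after centring within 5 Mb windows. The same holds for a trend with signal level from unequal enrichment, since r was 0.451 within level bins. A bias for GC-rich DNA stays open: regions near a gene end were lower by a log2 difference of −0.0279 in K303R, and gene ends stand only loosely for GC content. A hypothesis that remains is that E2 brings the wild-type and K303R receptors to regions that Y537S may occupy without hormone. NOL12, MAPKAPK3, LHPP, ATP2B2, ANO1 and CLIP2 cannot support it, since they reached the minimum mean only with their Y537S counts. RIBC2 and DUOX2 reached it without them, but all of these regions were chosen after their values were seen. The Y537S lists also carry another tag, and no replicate tests the hypothesis.

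The low Y537S ratios along chromosome 6 may come from a difference in DNA copy number between the cell lines. Weakly covered regions of chromosome 6, which were not used to see the pattern, had a median log2 ratio of −0.31 without E2, where the well-covered ones had −0.40 and the genome's weak regions 0.00. A loss of ERα binding along a whole chromosome was not tested, and neither was a batch difference. Ratios of Y537S to wild type at single genes of chromosome 6, such as MYB and PTPRK, therefore cannot be read as receptor effects alone.

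E2 ratios lay closest to 1 at the strongest regions, such as those of GREB1 and PGR. The spread of wild-type E2 ratios beyond counting error at regions of 200 or more fragments was 0.0728 of that at regions of 50 to 100 fragments. A limit on distinct fragments per position compresses such ratios, and correcting for it raised the value to 0.439 (bootstrap error 0.0129), still under the 0.75 set beforehand as the bound. The limit is thus a part of the pattern in these counts and is argued against as the whole of it. The narrowing was not particular to E2. In each comparison of a mutant with wild type, the corrected spread was also smaller at regions of 200 or more fragments. For K303R with E2 the log2 spread was 0.283 there, against 0.653 at regions of 50 to 100 fragments. For Y537S without E2 it was 0.367 against 0.697. Binding that is already near its maximum without added E2, in serum that may hold hormone, is a candidate explanation. It concerns the E2 ratios only, and these lists do not test it.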
